A study of Mus musculus with 12 samples.

How the data were processed

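The data are log2 expression values from 12 Affymetrix mouse exon arrays, deposited by the authors as a single table with a value per probe set and array. Per the labels, total RNA was extracted with Trizol from mammary glands of mice of the FVB/N strain, and biotin-labelled cRNA was prepared for hybridisation. Fibroblasts and epithelial cells were separated by gravity and grown in serum-containing medium before extraction, while endothelial cells were collected by fluorescence-activated sorting without culture. The cultured cells and the sorted cells therefore differ in handling, and a culture can hold more than a single cell type. Wild-type mice carried the floxed Pten alleles without Cre, and mutants carried the same alleles with Cre under the Fsp promoter. For epithelial and endothelial cells the mutant group refers to the genotype of the stroma of the mice.

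The log2 values were made by the authors with Affymetrix Expression Console and its RMA method, per the submitters' processing notes. RMA is a method that corrects background, normalizes between arrays and summarises probes on the log2 scale. Software versions, the annotation level of the probe sets and the genome build are not given in the sources used here. Array medians were 5.38, 5.41, 5.38 and 5.46 for the fibroblast arrays (wild type replicates 1 and 2, then Pten-null replicates 1 and 2), 5.21, 5.43, 5.53 and 5.41 for the epithelial arrays and 5.35, 5.44, 5.09 and 5.41 for the endothelial arrays in the same order. The values are not centred per gene, and larger values mean more signal; which arrays were normalized together is not given in the sources used here. Compression of small signals by the background step makes differences of low genes smaller than they may be in the RNA.

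Of 23238 probe sets, 14939 had a single gene symbol in the platform annotation, 989 had several and 7310 had no entry. Symbols were updated through Entrez gene numbers against a RefSeq gene table of assembly GRCm38.p6, used for names only, which matched 14884. Probe sets with several symbols or none were left out of the named results and analysed apart. For 131 genes with more than 1 probe set, the probe set with the highest mean over the 12 arrays was used, which left 14807 genes. A gene was tested in a cell type when its value lay above its array's 50th percentile in at least 2 of the 4 arrays.

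A linear model with a mean for each of the 6 groups was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, using lmFit and eBayes. Array weights were estimated per cell type, at 2.67 for fibroblasts, 0.742 for epithelial cells and 0.505 for endothelial cells, which correspond to relative standard deviations of 0.613, 1.16 and 1.41. The fit had 6 residual and 5.01 prior degrees of freedom. Mutant was set against wild type in each cell type, and the difference between changes was tested in the same model over genes above the filter in either cell type. P-values were adjusted by Benjamini-Hochberg within each comparison, with 0.05 as the threshold. With 2 arrays per group no exact permutation test can reach that threshold, so every p-value rests on the pooled spread of the model. Per the labels the replicates are biological; whether a replicate stands for an animal or a pool of animals is not given in the sources used here. A group of 2 is too small to test single arrays as outliers.

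A set of 39 gene lists covering pathways and cell type markers was fixed before the data were examined, as were the tests and most alternatives. Lists with at least 5 tested members were tested with limma's camera, at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera compares the genes of a list with all others. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in a single direction and does not compare them with other genes, were run beside it. Camera called 9 of 32 lists in fibroblasts, 19 of 33 in epithelial cells and 16 of 35 in endothelial cells, with the estimated correlation 0 in each, and fry called 5, 11 and 0. Of the lists called by camera at the preset correlation, fry also called 4, 11 and 0.

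Genes named in the text follow a rule set beforehand. It takes the tested genes that published work on this model named, the 8 largest rises and 8 largest falls past the threshold whose arrays did not overlap between groups, up to 4 members of smallest p from each described list, up to 6 genes called in 2 cell types and up to 5 genes per difference between cell types. Genes named outside it are said to have been chosen after their values were seen, or complete a count of list members past the test.

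The procedure was tested on simulated data drawn from the real means and spreads, with noise independent between genes and no array shifted or standing apart. The rates below hold for such data and may be too favourable for the real arrays. Of genes changed by 1 on the log2 scale, 49.2% were recovered in fibroblasts, 28.8% in epithelial cells and 21.3% in endothelial cells, and of genes changed by 2, 95.4%, 88.9% and 78.8%. Changes of 0.5 were recovered in 2.99%, 1.54% and 0% of cases, with 8, 6 and 5 false calls in the 3 simulations.

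Alternatives were quantile normalization over all arrays or within a cell type, median centring, no filter or the 60th percentile, every probe set or the mean per gene, equal weights, the 4 arrays of a cell type alone, a trended robust prior, the replicate number as a block, and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.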

Results

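Gene expression was measured on 12 Affymetrix exon arrays from mouse mammary glands, with 3 cell types and 2 genotypes. The cell types were cultured fibroblasts, cultured epithelial cells and endothelial cells sorted directly from the tissue. In the mutant mice Cre recombinase under the Fsp promoter deleted the floxed Pten gene, which encodes the phosphatase that opposes PI3K signalling, in stromal fibroblasts; wild-type mice carried the floxed gene without Cre. Each of the 6 groups had 2 arrays, described by the labels as biological replicates, from mice 9 weeks of age. Array medians lay between 5.09 and 5.53 on the log2 scale. The number of arrays limits the precision. The series set mutant against wild type within each cell type, to ask how Pten loss in fibroblasts affects the fibroblasts themselves and the neighbouring epithelial and endothelial cells.

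No probe set carried Pten as its only gene name in the annotation used, so the level of the targeted gene was not analysed here and the genotype labels were not checked by it. Changes are given as mutant minus wild type, on the log2 scale with their standard error (SE, 2 arrays per group), and adjusted p-values are limma's with Benjamini-Hochberg adjustment. A level below the array medians is not shown to be above background, and a change to or from it is a difference between RMA values, not a measured ratio of RNA. The lower group lay below in 96 of 607 called genes in fibroblasts, 104 of 404 in epithelial cells and 7 of 12 in endothelial cells. The median change of all tested genes was 0.0149 in fibroblasts, 0.145 in epithelial cells and -0.259 in endothelial cells. Quantile normalization over the 12 arrays moved these medians to -0.0233, -0.031 and -0.0366. The gene list test called camera compares each list with the other genes, and therefore reads relative to this shift. No list call in any cell type was kept when the correlation between genes was estimated from the data, and that p is given beside each list.

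Pten-null fibroblasts had higher levels of inflammatory cytokine and chemokine genes than wild-type fibroblasts, and of single metalloproteinase genes such as Mmp10 and Mmp9. Among the genes with lower levels were Ccn3, Igfbp2 and the contractile gene Myh11. Of 8552 genes tested, 382 were higher and 225 lower. Among the largest rises was that of Il1a, the cytokine interleukin 1 alpha, from 3.22 ± 1.06 to 9.15 ± 0.63 (SD, n = 2). Mmp10, the protease stromelysin 2, rose by 4.75 ± 0.30 and Lcn2, a secreted siderophore-binding lipocalin, by 4.47 ± 0.51. The wild-type levels of these 3 genes lay below the array medians. At the other end, Ccn3, a secreted matricellular protein, fell by 3.83 ± 0.29.

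Of 25 tested genes in the list of chemokines and inflammatory cytokines, 15 rose, 1 fell and 9 did not pass the test; adjusted over the list alone, 18 rose and 2 fell. Csf2, which encodes the growth factor GM-CSF, rose by 4.04 ± 0.31 (adjusted p = 2.49e-05). The neutrophil-attracting chemokines Cxcl1 and Cxcl5 rose by 2.78 ± 0.23 and 2.71 ± 0.30, and the cytokines Lif and Il6, chosen after their values were seen, by 2.10 ± 0.24 and 2.24 ± 0.32. The member that fell was the membrane-bound chemokine Cx3cl1, at -1.88 ± 0.23. The median of the list was 1.48, and camera gave adjusted p = 4.52e-12, against adjusted p = 0.519 with an estimated correlation. Markers of macrophages and other myeloid cells, which also make many of these factors, had a median change of 0.166, and none of the 15 tested passed.

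Among 27 matrix proteases and their inhibitors, 7 rose and 3 fell, and 10 and 4 did so adjusted over the list alone. Besides Mmp10, the gelatinase gene Mmp9 rose by 3.64 ± 0.25 and the collagenase gene Mmp8, chosen after its values were seen, by 3.17 ± 0.48. Mmp11, known as stromelysin 3, fell by 1.82 ± 0.20, as did Adamts12, a secreted metalloprotease, by 1.18 ± 0.14. Members moved in both directions, and camera did not call the list (adjusted p = 0.0777, and adjusted p = 0.775 with an estimated correlation). Fry called it higher (adjusted p = 0.0478).

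**Figure D1:**
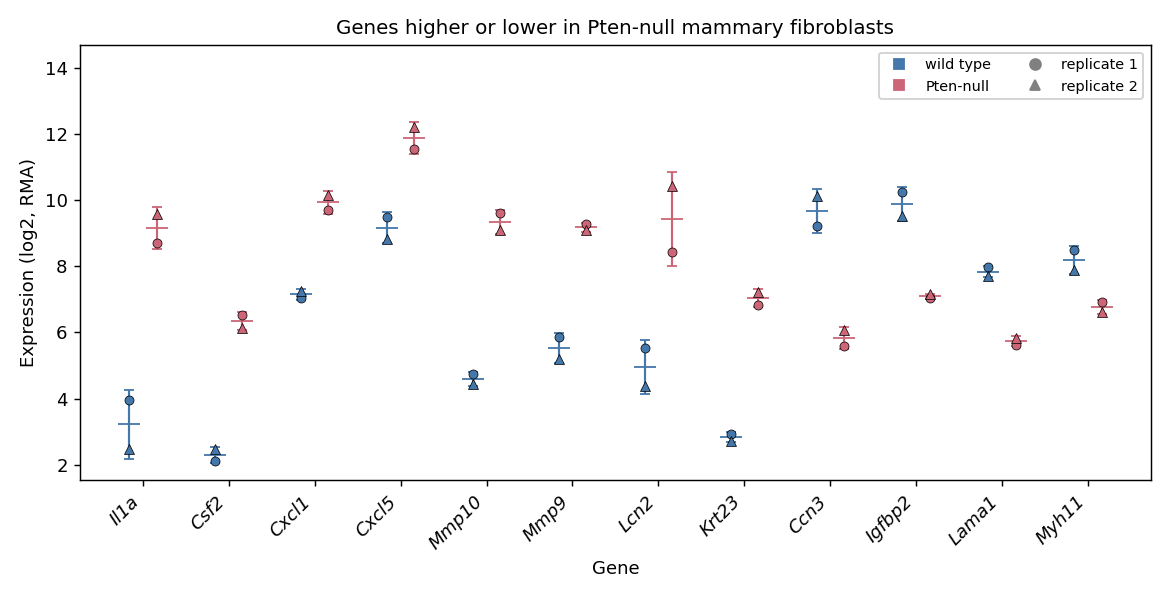
Expression of 12 genes in wild-type and Pten-null fibroblasts, on the log2 scale of the RMA values (vertical axis). Circles and triangles are the arrays of replicates 1 and 2, and bars are the mean ± SD of 2 arrays; Il1a lay at 3.96 and 2.47 in wild-type and at 8.70 and 9.59 in Pten-null arrays, and Ccn3 moved the other way.

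Other large changes fell outside these lists. The calcium-binding protein gene S100a3 rose by 4.25 ± 0.18, the keratin gene Krt23 from 2.83 ± 0.15 to 7.03 ± 0.27 (SD, n = 2), the metalloreductase gene Steap4 by 4.10 ± 0.38 and Crabp1, which encodes a retinoic acid binding protein, by 3.84 ± 0.40. Lower genes included Gjb2, which encodes the gap junction protein connexin 26, at -2.84 ± 0.18, and the insulin-like growth factor binding protein gene Igfbp2 at -2.78 ± 0.28. Sned1 and Podn, which encode secreted matrix proteins, fell by 2.76 ± 0.19 and 2.48 ± 0.30. The globin gene Cygb, the secreted C1q family member C1qtnf3 and the sodium channel gene Scn7a fell by 2.54 ± 0.27, 2.66 ± 0.19 and 2.38 ± 0.30. Within the matrix lists, Eln, the gene for elastin, fell by 2.14 ± 0.22 and the laminin chain gene Lama1 by 2.10 ± 0.15, whereas Tnc, the gene for tenascin C, rose by 1.10 ± 0.14. Of 24 proteoglycans and matricellular proteins 2 rose and 3 fell, with 3 and 4 adjusted over the list alone, and camera did not call the list (adjusted p = 0.0624, and adjusted p = 0.775 with an estimated correlation).

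Of 24 TGF-beta targets and contractile genes, 3 fell and none rose, with 5 lower adjusted over the list alone. They were the smooth muscle myosin gene Myh11 at -1.41 ± 0.18, the collagen-binding integrin gene Itga11 at -1.41 ± 0.25 and Tgfbi, a secreted matrix protein, at -0.68 ± 0.16. Camera called the list lower (adjusted p = 0.00155, and adjusted p = 0.775 with an estimated correlation), a call that ended without wild-type replicate 1 (adjusted p = 0.0604) or without Pten-null replicate 2 (adjusted p = 0.189). Pericyte and smooth muscle markers were called lower as well (adjusted p = 0.0135, and adjusted p = 0.519 with an estimated correlation), with 1 of 8 members, Myh11, past the test and 3 adjusted over the list alone; without wild-type replicate 1 adjusted p was 0.106. In the Notch list, 2 of 11 members fell, the ligand gene Jag1 by 0.71 ± 0.14 and Dtx4 by 1.17 ± 0.14, also 2 adjusted over the list alone; camera gave adjusted p = 0.0135, and adjusted p = 0.775 with an estimated correlation.

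Genes of cholesterol synthesis were higher as a group, with a median of 0.372 over 17 members, although only Hsd17b7 passed on its own (0.60 ± 0.13); 6 passed adjusted over the list alone. Camera gave adjusted p = 0.00237, and adjusted p = 0.775 with an estimated correlation. In fatty acid synthesis and lipogenesis 3 of 17 members rose, Elovl6 by 1.05 ± 0.24, Scd1 by 0.71 ± 0.17 and Dgat2 by 0.88 ± 0.21, also 3 adjusted over the list alone (camera adjusted p = 0.0406, and adjusted p = 0.845 with an estimated correlation); the call ended under quantile normalization (adjusted p = 0.0525), without wild-type replicate 1 (0.106) and without Pten-null replicate 1 (0.0987). In the p53 list Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 1.00 ± 0.24 and the phospholipid transfer protein gene Pltp fell by 1.27 ± 0.26 (camera adjusted p = 0.0343, and adjusted p = 0.775 with an estimated correlation). Adjusted over that list alone, 8 of 21 members were higher and 2 lower, and the call ended under each of the 3 other scalings (highest adjusted p = 0.0652), without wild-type replicate 2 (0.0727) and without Pten-null replicate 1 (0.144). Of 7 ribosomal protein genes tested only Rpl22 fell, both over all genes and adjusted over the list alone (camera adjusted p = 0.0342, and adjusted p = 0.775 with an estimated correlation), and that call ended without wild-type replicate 2 (0.189) or Pten-null replicate 2 (0.105).

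Of 7 tested genes that published work on this mouse model has named, 3 rose and none fell: Mmp9, the chemokine gene Ccl3 by 1.57 ± 0.33 and the transcription factor gene Ets2 by 0.67 ± 0.14. Adjusted over the list alone 4 rose. These genes may have been picked from the same arrays, so the list is not independent evidence of its direction (camera adjusted p = 0.00621, and adjusted p = 0.522 with an estimated correlation). The remaining members did not pass: Emilin2, an elastin-associated glycoprotein, at 0.48 ± 0.18, the collagen cross-linking enzyme gene Loxl2 at 0.23 ± 0.13, the procollagen protease gene Bmp1 at -0.09 ± 0.11 and Col1a1 at -0.02 ± 0.20. The call of Ets2 ended in 5 of 15 other settings, among them leaving out either wild-type array or Pten-null replicate 1 (highest adjusted p = 0.507), and that of Ccl3 in 4, among them leaving out wild-type replicate 2 or Pten-null replicate 2 (highest adjusted p = 0.273).

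Besides Il1a, Mmp10 and Lcn2, the lower group lay below the array medians for Csf2, Mmp8, S100a3, Krt23, Gjb2, C1qtnf3, Scn7a and Eln. The fit over all 12 arrays gave fibroblast arrays the highest weight, because their replicates differed least. With equal weights 88 genes passed in place of 607, and leaving out wild-type replicate 1 or 2 left 289 or 188.

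Epithelial cultures from mice with Pten-null stroma had higher levels of fibrillar collagens, basement membrane components and other matrix genes than wild-type cultures, and lower levels of single epithelial genes such as Dsg3, Sfn and Krt17. Of 8789 genes, 366 were higher and 38 lower, against 305 and 70 under quantile normalization and 317 and 69 under median centring. Among the largest rises was that of Aldh1a1, which encodes a retinaldehyde dehydrogenase, from 3.63 ± 0.63, below the array medians, to 9.14 ± 0.47 (SD, n = 2). Markers of fibroblasts rose in the same arrays: 12 of 15 tested markers were higher and none lower, with 14 higher adjusted over the list alone. Among them were S100a4, the gene for the fibroblast-specific protein Fsp1, which rose by 4.18 ± 0.55 from a level below the array medians, Col1a2 at 1.89 ± 0.28, Pdgfrb at 1.44 ± 0.25 and Col3a1 at 2.29 ± 0.42 (camera adjusted p = 2.91e-12, and adjusted p = 0.08 with an estimated correlation).

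The change of a gene in the epithelial cultures went with the difference between fibroblasts and wild-type epithelial cells. With a different wild-type epithelial array on each side, a computation chosen after the values were seen, Pearson's r across genes, which are not independent replicates, was 0.485 and 0.535 in the 2 orders. A wild-type array in place of the mutant ones, with the other wild-type array on both sides, gave 0.196 and 0.255. Among genes at least 2-fold higher in both fibroblast groups, 82.6% and 97% were higher in the mutant arrays in the 2 orders. Over all genes these shares were 53.8% and 75.9%. The wild-type array in their place gave 78.4% and 49.7%, so in the first order the wild-type arrays differed from each other in nearly as many of these genes. Among 3493 genes lower in both fibroblast groups than in wild-type epithelial cells, 10 were called higher and 38 lower, while all 356 calls among the other 5296 genes were higher; this grouping uses the same wild-type arrays as the test, which favours such a split. Every matrix result below stands beside the rise of fibroblast markers.

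**Figure D2:**
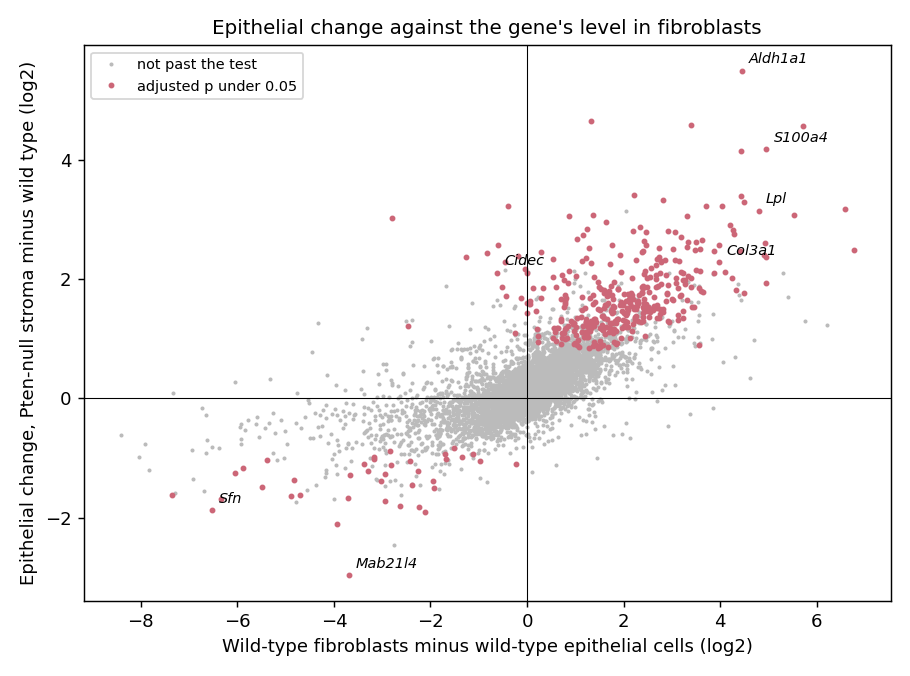
Change of each of 8789 genes in epithelial cultures from mice with Pten-null stroma (vertical axis, log2) against the difference between wild-type fibroblasts and wild-type epithelial cells (horizontal axis, log2). Each point is a gene, red for those past the test, 366 above and 38 below 0; both axes subtract the same wild-type epithelial arrays, which alone tilts the points upwards.

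Of 26 collagens and genes of fibrillar matrix 17 rose and none fell, with 23 higher adjusted over the list alone and a mean of 1.68. The collagen cross-linking enzyme genes Loxl2 and Loxl3 rose by 2.30 ± 0.25 and 2.81 ± 0.31, the collagen gene Col5a2 by 2.11 ± 0.24 and the matrix glycoprotein gene Fbln2 by 1.75 ± 0.24. Camera gave adjusted p = 1.17e-19, and adjusted p = 0.08 with an estimated correlation. In the basement membrane list 7 of 16 rose, and 10 rose and 1 fell adjusted over the list alone, with the laminin gene Lama2 at 3.34 ± 0.38 and the type IV collagen genes Col4a1 and Col4a2 at 1.84 ± 0.21 and 2.12 ± 0.19 (camera adjusted p = 5.22e-07, and adjusted p = 0.0834 with an estimated correlation). Proteoglycans and matricellular genes rose in 6 of 21 cases, led by Aspn, the small proteoglycan asporin, at 4.58 ± 0.72, and in 10 adjusted over the list alone (camera adjusted p = 0.000978, and adjusted p = 0.362 with an estimated correlation). Matrix proteases rose in 6 of 25 cases, among them the cathepsin gene Ctsk at 2.88 ± 0.42 and Mmp19 at 2.80 ± 0.37 (camera adjusted p = 0.00606, and adjusted p = 0.402 with an estimated correlation); 11 rose and 3 fell adjusted over the list alone, and the call ended without wild-type replicate 2 (adjusted p = 0.0692).

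Camera called both lists of epithelial markers lower, though few or no members passed. Of 17 basal markers 3 fell and 2 rose, and 9 fell and 2 rose adjusted over the list alone. The desmosomal cadherin gene Dsg3 fell by 1.49 ± 0.23, Sfn, which encodes the 14-3-3 sigma protein, by 1.88 ± 0.35 and Krt17 by 1.63 ± 0.39, whereas the myosin kinase gene Mylk rose by 1.28 ± 0.30. Camera called the list lower (adjusted p = 2.71e-08, and adjusted p = 0.08 with an estimated correlation). None of 19 luminal markers passed, over all genes or adjusted over the list alone, but their median was -0.422, with the adhesion gene Cdh1 at -0.91 ± 0.26 and the keratin gene Krt18 at -0.98 ± 0.31 (camera adjusted p = 3.3e-06, and adjusted p = 0.18 with an estimated correlation). The 38 lower genes also held Mab21l4 at -2.97 ± 0.28, the ATP-gated channel gene P2rx2 at -2.11 ± 0.33, Gjb2 at -1.90 ± 0.35, the ligand gene Wnt7a at -1.81 ± 0.25, the cytokine gene Tnf at -1.72 ± 0.26, the integrin gene Itgb6 at -1.69 ± 0.27 and the actin-bundling protein gene Lcp1 at -1.83 ± 0.39.

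Of 24 interferon response genes 3 rose and 10 did so adjusted over the list alone: Ifit1 at 2.85 ± 0.50, Ifit2 at 1.30 ± 0.24 and the signal transducer gene Stat2 at 1.18 ± 0.23 (camera adjusted p = 3.89e-05, and adjusted p = 0.402 with an estimated correlation). Ifit1 and Ifit2 lay at least 2-fold higher in both fibroblast groups than in wild-type epithelial cells. Over the 13 members lower in fibroblasts, of which 0 passed, the list had a median of 0.525 and a camera adjusted p of 1.9e-06, against adjusted p = 0.269 with an estimated correlation. Glycolysis and hypoxia targets rose in 7 of 21 cases, with the prolyl hydroxylase genes P4ha2 and Egln3 at 1.78 ± 0.25 and 2.41 ± 0.42 and 12 higher adjusted over the list alone (camera adjusted p = 3.89e-05, and adjusted p = 0.402 with an estimated correlation); the call ended without wild-type replicate 2 (adjusted p = 0.0954). Adipocyte markers rose in 4 of 10 cases, also 4 adjusted over the list alone: the adipogenic transcription factor gene Pparg at 2.04 ± 0.24, the lipoprotein lipase gene Lpl at 3.15 ± 0.42, the lipid droplet protein gene Cidec at 2.11 ± 0.33 and the fatty acid binding protein gene Fabp4 at 2.36 ± 0.37 (camera adjusted p = 0.000159, and adjusted p = 0.402 with an estimated correlation). The adipocyte call ended without replicate 2 from Pten-null stroma (adjusted p = 0.507). Myeloid markers had a median of 1.10 with 1 of 12 past the test, Cd68 at 1.86 ± 0.46, and 2 adjusted over the list alone (camera adjusted p = 0.0218, and adjusted p = 0.594 with an estimated correlation). That call ended without wild-type replicate 2 (0.616) or without replicate 1 from Pten-null stroma (0.14).

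Targets of PI3K feedback and FOXO rose in 5 of 33 cases, also 5 adjusted over the list alone, among them the glucocorticoid-induced gene Tsc22d3 at 2.13 ± 0.34 and the thioredoxin-binding protein gene Txnip at 1.58 ± 0.26 (camera adjusted p = 0.02, and adjusted p = 0.474 with an estimated correlation). In the p53 list the receptor gene Eda2r at 2.57 ± 0.36 and the zinc finger gene Zmat3 at 1.28 ± 0.29 rose, 2 of 23 by either adjustment (camera adjusted p = 0.0356, and adjusted p = 0.465 with an estimated correlation). Both calls ended without wild-type replicate 2 (0.116 and 0.871) or without replicate 2 from Pten-null stroma (0.346 and 0.53). Among TGF-beta targets Itga11 rose by 1.94 ± 0.47 and the cytoskeletal protein gene Pdlim7 fell by 1.05 ± 0.22, 1 gene each way of 25 by either adjustment, with a median of -0.257 (camera adjusted p = 9.56e-05, and adjusted p = 0.402 with an estimated correlation). Cholesterol synthesis genes had a median of -0.278 with 0 of 17 past either test (camera adjusted p = 8.48e-05, and adjusted p = 0.402 with an estimated correlation).

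Further single genes were among the largest rises, all in the arrays with raised fibroblast markers. They were the flavin monooxygenase gene Fmo2 at 4.66 ± 0.54, Itgbl1, an integrin beta-like protein, at 4.59 ± 0.78, the protease inhibitor gene Serpina3n at 4.15 ± 0.39, the costimulatory receptor ligand gene Cd80 at 3.42 ± 0.54 and the extracellular glutathione peroxidase gene Gpx3 at 3.40 ± 0.49. Itgbl1 reached a level above both wild-type and Pten-null fibroblasts, which held it at 7.345 and 6.499. The others in this group did not lie above both. Of the 7 model genes tested, Loxl2, Emilin2 at 2.02 ± 0.35 and Col1a1 at 1.70 ± 0.38 rose, and 4 rose and 1 fell adjusted over the list alone. As above, this list is not independent evidence (camera adjusted p = 0.0485, and adjusted p = 0.402 with an estimated correlation), and its call ended without wild-type replicate 1 (0.0715) or 2 (0.116). The call of Col1a1 ended in 8 of 15 other settings, among them each of the 3 other scalings and leaving out wild-type replicate 1 or either array from Pten-null stroma (highest adjusted p = 0.433). Mmp9 at -1.74 ± 0.47, Ccl3 at 1.68 ± 0.63, Bmp1 at 0.38 ± 0.21 and Ets2 at -0.32 ± 0.27 did not pass.

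The lower group lay below the array medians for Aldh1a1, S100a4, Lama2, Aspn, Mab21l4, P2rx2, Wnt7a, Ifit1, Ifit2, Egln3, Pparg, Cidec, Fabp4, Tsc22d3, Eda2r, Fmo2, Itgbl1 and Cd80. The epithelial counts rested on both mutant arrays, since 10 genes passed without replicate 1 from Pten-null stroma and 85 without replicate 2, against 404. A fit of the 4 epithelial arrays alone called 168.

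Endothelial cells sorted from mice with Pten-null stroma had higher levels of single genes of fat cells and lipid synthesis, such as Retn, Cidec and Fasn, than those from wild-type mice. Of 8525 genes only 12 passed, 8 higher and 4 lower. Among the largest rises was that of Cyp2e1, a cytochrome P450 gene, from 5.41 ± 0.11, near the array medians, to 9.72 ± 1.43 (SD, n = 2). The adipokine gene Retn rose by 3.39 ± 0.47 from a level below the array medians, the fatty acid synthase gene Fasn 7.99-fold and Cidec 7.58-fold. The fold of Cidec depended on the array, with values of 8.445 and 9.88 from Pten-null stroma and 5.989 and 6.491 in wild type. Pcx, which encodes pyruvate carboxylase, the fatty acid transporter gene Slc27a1, the amino acid transporter gene Slc7a10 and the acyltransferase gene Gpat3 rose by 3.06 ± 0.45, 3.05 ± 0.33, 2.48 ± 0.40 and 2.20 ± 0.34, the last 2 from below the array medians.

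Adipocyte markers had a median change of 1.15. Of 16 tested, 2 rose (Cidec and Retn), and 10 did so adjusted over the list alone. The brown fat uncoupling protein gene Ucp1, below the array medians in wild-type cells, stood at 4.44 ± 0.73 and the lipid droplet gene Plin1 at 2.34 ± 0.48 without passing. Camera gave adjusted p = 4.33e-28, and adjusted p = 0.135 with an estimated correlation. In fatty acid synthesis and lipogenesis 1 of 20 genes rose, Fasn, and 8 adjusted over the list alone; the lipogenic transcription factor gene Mlxipl, at 1.56 ± 0.27, did not pass over all genes (camera adjusted p = 2.47e-24, and adjusted p = 0.135 with an estimated correlation). Glycolysis genes were called higher with 0 of 19 past the test and 1, the hexokinase gene Hk2 at 1.78 ± 0.41, adjusted over the list alone (camera adjusted p = 9.21e-08, and adjusted p = 0.328 with an estimated correlation). Pparg and Fabp4, named here after their values were seen, were at -0.41 ± 0.29 and -0.45 ± 0.45 from wild-type levels of 10.6 and 11.3.

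**Figure D3:**
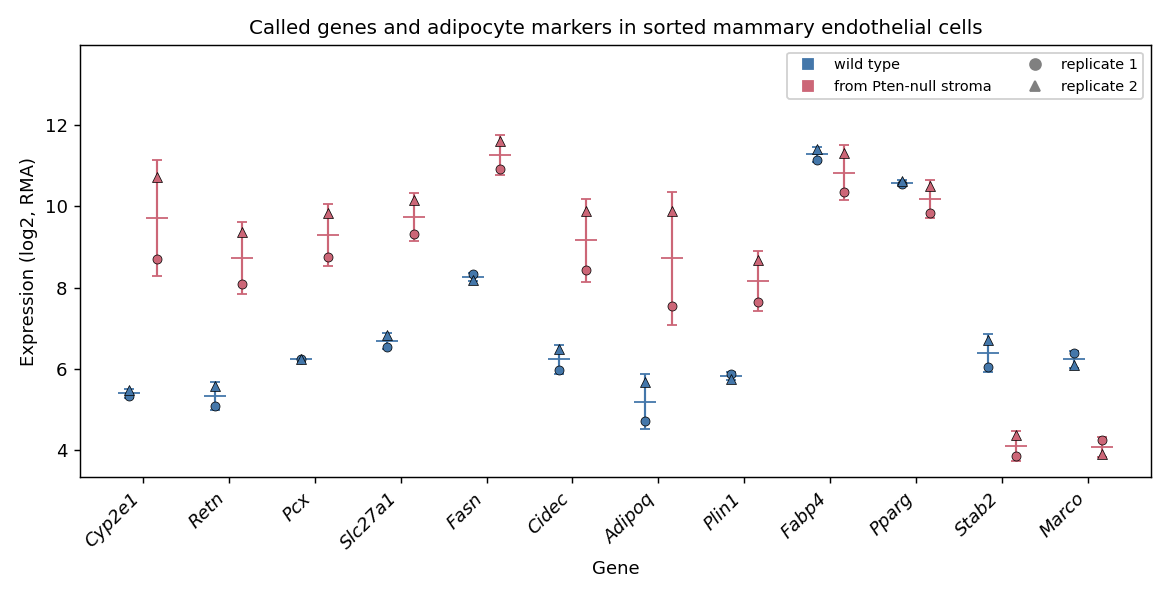
Expression of 12 genes in endothelial cells sorted from wild-type mice and from mice with Pten-null stroma, on the log2 scale of the RMA values (vertical axis). Circles and triangles are the arrays of replicates 1 and 2, and bars are the mean ± SD of 2 arrays; Fasn lay at 8.33 and 8.19 in wild-type arrays and at 10.9 and 11.6 in the others, while Fabp4 and Pparg overlapped or lay below.

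The 4 lower genes were Stab2 and Marco, which encode scavenger receptors, at -2.27 ± 0.30 and -2.16 ± 0.31, the neuronal adhesion gene Astn1 at -1.96 ± 0.25 and the transmembrane protein gene Tmem255a at -1.92 ± 0.27, each reaching a level below the array medians. Cell cycle genes had a median of -0.896, below the general shift, but none of 25 passed and 1, Mki67 at -2.11 ± 0.47, did so adjusted over the list alone (camera adjusted p = 3.04e-05, and adjusted p = 0.587 with an estimated correlation). The cell cycle call ended without wild-type replicate 1 (adjusted p = 0.129) or without replicate 2 from Pten-null stroma (adjusted p = 0.629). Lymphatic markers were called higher with 0 of 6 past either test, among them Lyve1 at 0.96 ± 0.59 and Pdpn at 1.03 ± 0.40 (camera adjusted p = 0.000213, and adjusted p = 0.328 with an estimated correlation); their median was 1.12 without replicate 1 from Pten-null stroma and -0.1 without replicate 2. Oxidative phosphorylation genes had a median of -0.026 and a mean of 0.017, and were called higher relative to the other genes with 0 of 26 past either test (camera adjusted p = 0.000991, and adjusted p = 0.587 with an estimated correlation). The median of these genes was 0.272 without replicate 1 from Pten-null stroma and -0.291 without replicate 2.

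Camera also called lists of markers of other cell types higher in the arrays with higher lipid genes, without a member past the test over all genes. Luminal epithelial markers had a median of 0.274 with 0 of 17 past either test, Krt18 standing at 0.84 ± 0.38 (camera adjusted p = 7.08e-09, and adjusted p = 0.135 with an estimated correlation). Myeloid markers had a median of 0.533, with the complement genes C1qa and C1qc at 2.06 ± 0.76 and 1.87 ± 0.64 and the leukocyte gene Cd52 at -2.05 ± 0.56, none of the 11 past the test and 1, Cd52, lower adjusted over the list alone (camera adjusted p = 1.93e-06, and adjusted p = 0.328 with an estimated correlation). Fibroblast markers had a median of 0.225 with 0 of 15 past either test (camera adjusted p = 0.00203, and adjusted p = 0.571 with an estimated correlation), and Schwann and nerve markers a median of 0.332 with 0 of 7 past either test (camera adjusted p = 0.00203, and adjusted p = 0.294 with an estimated correlation). The luminal, myeloid, fibroblast and Schwann calls ended without replicate 1 from Pten-null stroma, at adjusted p = 0.088, 0.151, 0.994 and 0.126. The milk protein list was not called (adjusted p = 0.65, and adjusted p = 0.871 with an estimated correlation), and its member Csn1s2a, a casein gene, stood at -2.39 ± 0.55 without passing over all genes. Of the model genes none of 8 passed, with Mmp9 at -1.90 ± 0.57, Ccl5 at -1.51 ± 0.60 and Col1a1 at 1.10 ± 0.46.

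Replicate 1 from Pten-null stroma stood apart from the other arrays, with a median of 5.09 and a correlation of 0.948 with its replicate, against at least 0.966 for the other pairs. Limma called 218 genes without it (163 higher) and 4981 without its replicate (293 higher), 0 without wild-type replicate 1 or 2 (45 and 52 at unadjusted p under 0.05), and 54 after quantile normalization, 79.6% of them higher against 66.7% as deposited. Median centring called 44 (75% higher), and the endothelial arrays fitted alone called 0 (367 at unadjusted p under 0.05).

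Whether a change differed between cell types was tested as a difference of changes. Against fibroblasts, this sets Pten loss in the cells themselves against Pten loss in the stroma around wild-type cells. Between epithelial cells and fibroblasts 402 of 9182 genes differed, 314 with the more positive change in epithelial cells. Il1a, Csf2 and Mmp9, which rose in fibroblasts, had changes of -0.89, -1.83 and -1.74 in epithelial cells, so that the differences were -6.82 ± 0.86, -5.87 ± 0.67 and -5.39 ± 0.53 (adjusted p = 0.00196, 0.00121 and 0.000547). Ccn3 and Itgbl1 differed in the other direction, by 5.54 ± 0.61 and 5.44 ± 0.88. Between endothelial cells and fibroblasts 39 of 9292 genes differed, 16 with the more positive change in endothelial cells, among them Ucp1, low in wild-type endothelial cells, at 4.71 ± 0.79. The other 23 held Il1a, Mmp9, Krt23 and Mmp10, at -6.23 ± 1.00, -5.54 ± 0.62, -4.75 ± 0.35 and -4.36 ± 0.74. Between endothelial and epithelial cells 26 of 9386 differed, 5 more positive in endothelial cells and 21 more negative. Among the 21 were the glutamate receptor gene Gria3 at -4.20 ± 0.43, Aldh1a1 at -4.04 ± 0.63, the histocompatibility gene H2-M11 at -3.93 ± 0.53, Adam23, a membrane protein of the ADAM family, at -3.70 ± 0.58, and among the 5 was Cyp2e1 at 4.03 ± 0.67.

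These differences depended on scaling and on single arrays. Quantile normalization raised the endothelial counts to 105 against fibroblasts, with 64.8% of genes more positive in endothelial cells in place of 41%. Against epithelial cells the count rose to 64, with 25 more positive in endothelial cells and 39 more negative, in place of 5 and 21. Neither endothelial comparison had a call by limma without either endothelial wild-type array (unadjusted p under 0.05 in 131 and 148 genes against fibroblasts, and in 322 and 294 against epithelial cells). Without replicate 1 or 2 of the endothelial cells from Pten-null stroma 337 and 4515 genes differed against fibroblasts, and 150 and 3499 against epithelial cells. Without fibroblast wild-type replicate 1 or 2, 22 and 16 genes differed between endothelial cells and fibroblasts. Between endothelial and epithelial cells, leaving out epithelial wild-type replicate 1 or 2 gave 77 and 15 genes, and leaving out epithelial replicate 1 from Pten-null stroma gave 0 by limma (666 at unadjusted p under 0.05). The 402 genes between epithelial cells and fibroblasts became 66 or 152 without replicate 1 or 2 of the epithelial cells from Pten-null stroma, and 249 without fibroblast wild-type replicate 2.

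Fibroblasts and epithelial cells shared 77 called genes. Of these 42 were higher in both, against 13.7 from independent lists (Fisher's exact test, p = 4.81e-11), and 31 were lower in fibroblasts but higher in epithelial cells, against 8.62 (p = 3.74e-10). Of the 366 higher epithelial genes 285 lay at least 2-fold higher in both fibroblast groups than in wild-type epithelial cells. Such genes can raise the overlap in either direction without a shared response, and the test takes genes as independent. Fmo2, the transglutaminase gene F13a1 and Cd80 rose in both, by 3.64, 2.32 and 2.23 in fibroblasts and by 4.66, 2.97 and 3.42 in epithelial cells. Scn7a and C1qtnf3 fell in fibroblasts and rose by 2.51 and 1.93 in epithelial cells, whereas Gjb2 fell in both. Scn7a and C1qtnf3 were not among the 285. Pten-null fibroblasts held them at 3.994 and 4.591, less than 2-fold above wild-type epithelial cells at 3.353 and 4.161. Without replicate 1 or 2 of the epithelial cells from Pten-null stroma 2 and 13 genes were shared, and without fibroblast wild-type replicate 1 or 2, 44 and 20. Pcx was the only gene called in all 3 cell types, at 2.04 in fibroblasts, 1.49 in epithelial and 3.06 in endothelial cells. Across all genes tested in both cell types of a pair, which are not independent replicates, the changes had Pearson correlations of 0.056 for fibroblasts with epithelial cells, 0.033 for fibroblasts with endothelial cells and 0.067 for epithelial with endothelial cells. The Spearman correlations were 0.071, -0.014 and -0.054, so the sign turned for both endothelial pairs.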

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

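The tests of myeloid and of epithelial markers in the fibroblasts, the comparison over all genes of the mixture below whether called or not, and the correlation with separate wild-type arrays were chosen only after the result was seen. The changes differed between cell types, by a test of the difference itself, in 402 genes between epithelial cells and fibroblasts, 39 between endothelial cells and fibroblasts and 26 between endothelial and epithelial cells. Between epithelial cells and fibroblasts the differences were -6.82 for Il1a, -5.87 for Csf2, -5.39 for Mmp9, 5.54 for Ccn3, 5.44 for Itgbl1, 2.07 for Loxl2 and 1.72 for Col1a1, on the log2 scale. Between endothelial cells and fibroblasts they were -6.23 for Il1a, -5.54 for Mmp9, -4.75 for Krt23, -4.36 for Mmp10 and 4.71 for Ucp1. Between endothelial and epithelial cells they were -4.2 for Gria3, -4.04 for Aldh1a1, -3.93 for H2-M11, -3.70 for Adam23, -2.50 for Loxl2 and 4.03 for Cyp2e1. Cultured and sorted cells differ in handling as well as in type, so a difference against endothelial cells is not one of cell type alone. A difference between epithelial cells and fibroblasts is not one of cell type alone either. The fibroblasts are Pten-null themselves, whereas the epithelial cells are wild type, from mice with Pten-null fibroblasts. The epithelial changes also went with fibroblast level, so fibroblast content of the cultures may enter this difference.

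Probe sets without a single gene name, which no comparison in the report uses, also held changes. Of 3270 tested in fibroblasts 82 passed, 51 higher and 31 lower; of 3099 in epithelial cells 24 passed, and of 3361 in endothelial cells none did by limma. The largest change, in fibroblasts, was 4.67 on the log2 scale.

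The first pattern is the rise of 366 genes in epithelial cultures from mice with Pten-null stroma, 285 of which lay at least 2-fold higher in both fibroblast groups than in wild-type epithelial cells. More fibroblasts in these cultures may account for part of it. Change and fibroblast level correlated across genes, which are not independent replicates, at 0.485 and 0.535 with separate wild-type arrays. A shared array without change gave 0.196 and 0.255. The share of fibroblast-high genes that were higher was 82.6% and 97% with separate arrays, and 78.4% and 49.7% without change. The wild-type cultures thus differed from each other too. With the share of fibroblasts set by 13 markers (median 27.4%, range 1.36% to 90.2%; 44.8% for replicate 1 and 18.4% for replicate 2), the observed change of the 285 genes exceeded the prediction by a median of 0.545, past the bound set beforehand against fibroblasts as the cause, and 86.7% of them lay above it, as a response of epithelial cells would need. That bound was wrong for this purpose, because the share moved with the array used, the profile of the added cells was assumed and calling a gene for being higher favours an excess; over all 864 such genes, called or not, the median excess was 0.209 with quartiles of -0.0788 and 0.498. Of the higher genes 2.73%, 10 in number, were lower in both fibroblast groups, and some of the margins were near 0. That share lies between the 2% set beforehand for fibroblasts as the cause and the 5% set against them. The remaining 71 higher genes, between these parts, rose by a median of 1.44, against 0.227 predicted at the median share. Their excess had quartiles of 0.808 and 1.56, which argues against fibroblasts of the measured profile as their only source. Calling a gene for being higher favours an excess here too. For the whole rise, a mixture with fibroblasts, cells of another type and a response of epithelial cells to the stroma cannot be told apart with 2 cultures per group.

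The second pattern is the rise of adipocyte genes in sorted endothelial cells from mice with Pten-null stroma. The array that stands apart is argued against as its only source, because without replicate 1 the median of the list was 1.37 (camera adjusted p = 2.96e-23). Without replicate 2 the median of the list was 0.795, so the rise was smaller in replicate 1 than in replicate 2. RNA from adipocytes stays open, since 11 of 18 markers, 61.1%, were higher in both arrays than in both wild-type arrays. This was short of the 75% that was set beforehand for this source and above the 50% set against it. The second part of that prediction, on markers below the array median in wild-type cells, was met, with a median change of 3.39 over 5 markers. Any cause of the pattern would raise such markers. Among the markers, named here after their values were seen, Fabp4, Aqp7, Pparg and Lpl lie high in wild-type endothelial cells and were not higher in both arrays, while Car3 and Pnpla2, about as high, changed by 1.22 and 1.08, and Lep, Slc2a4 and G0s2, at lower levels, by -0.31, 0.17 and 0.27. Fluorescence sorting should remove fat cells yet not free RNA, and adipocyte RNA and a change in the endothelial cells cannot be told apart with 2 arrays per group.

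The last pattern is the rise of chemokine and cytokine genes in Pten-null fibroblasts. More macrophages or other cells with the myeloid markers are argued against by these markers, whose median change was 0.166, against 1.48 for the chemokine list. Their quartiles were 0.0137 and 0.478 and the highest value 0.747, over the 15 of 22 markers on the array that passed the filter. Granulocytes were not tested, since only 2 members of the mast cell and granulocyte list passed the filter. Some genes outside the myeloid list that leukocytes can express, named after their values were seen, were called higher in Pten-null fibroblasts. Cd53 went from 9.587 to 10.819, F13a1 from 6.548 to 8.868 and Cd80 from 5.793 to 8.023. The argument therefore covers only cells with the listed markers. Epithelial cells are argued against by luminal and basal markers, with a median of 0.0134, quartiles of -0.192 and 0.338 and a highest value of 1.29, for Krt19 (14 of the 39 passed the filter, 3 were called higher and 2 lower); the abundant Krt18, named after its values were seen, lay at 13.0 in wild-type epithelial cells and at 4.98 and 4.79 in wild-type and Pten-null fibroblasts. Scaling and weighting are argued against, for the list set against the other genes, by the highest camera adjusted p of 2.58e-11 over 6 other settings. A shift common to all genes largely drops out of camera, so this is a weak test of scaling. Calls of single genes did depend on weighting, with 88 fibroblast genes under equal weights in place of 607. An effect of the Pten genotype remains a hypothesis, since differences between cultures were not tested, and with an estimated correlation between genes the list had an adjusted p of 0.519.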

How the results depend on the processing

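The counts over subsets of genes, chosen from levels in other cell types or from marker lists, were added only after the result was seen. The cause was not tested for any change below unless the setting itself shows it. Of the results for single genes 5540 stayed on the same side of the threshold, 484 lost it and 247 gained it. No gene that had passed before the change of setting reversed, and for genes that had not passed the direction was not compared. Of the results for called gene lists 534 kept their direction and the threshold, 135 lost the threshold and 4 reversed.

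Scaling moved the endothelial results: 54, 44 and 53 genes passed in place of 12 under quantile normalization, median centring and quantile normalization within a cell type. The differences rose to 105, 101 and 111 against fibroblasts and to 64, 64 and 66 against epithelial cells, and the shared genes to 6, 6 and 6 with fibroblasts and 7, 7 and 7 with epithelial cells. Lower calls in epithelial cells rose from 38 to 70, 69 and 70. Endothelial gene lists called under quantile normalization were 9 in place of 16.

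Without the filter fibroblasts and epithelial cells shared 50 genes in place of 77, epithelial and endothelial cells 1, and the correlations with endothelial changes were -0.02 for fibroblasts and -0.061 for epithelial cells; the 60th percentile gave 0.06 for fibroblasts. Testing every probe set, with more tests to adjust for, gave 4 endothelial genes, 261 differences between epithelial cells and fibroblasts, 15 between endothelial cells and fibroblasts and 10 between endothelial and epithelial cells, and 40, 0 and 0 shared genes.

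Equal weights gave 88 fibroblast and 46 endothelial genes, 225 differences between epithelial cells and fibroblasts, 233 between endothelial and epithelial cells, and 17, 3 and 8 shared genes. The 4 arrays of a cell type alone, with fewer degrees of freedom, gave 360, 168 and 0 genes in fibroblasts, epithelial and endothelial cells (367 endothelial genes at unadjusted p under 0.05) and 24, 0 and 0 shared genes. A trended robust prior gave 6 endothelial genes and 61 differences between endothelial and epithelial cells. The labels do not say that a replicate number marks a shared animal or day, and changes of the same number correlated weakly; with the replicate block 33 endothelial genes passed, 92 and 107 differences against fibroblasts and epithelial cells, and 116, 5 and 6 shared genes. Of epithelial genes lower in fibroblasts 48 passed, with 8 lists. With an estimated correlation 0, 0 and 0 lists were called.

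Leaving out 1 array, where the lone array of a group is assumed to vary like the others, gave 188 to 474 fibroblast, 10 to 503 epithelial and 0 to 4981 endothelial genes. The differences ranged over 66 to 500 between epithelial cells and fibroblasts, 0 to 4515 between endothelial cells and fibroblasts and 0 to 3499 between endothelial and epithelial cells. Shared genes ranged over 2 to 94, 0 to 172 and 0 to 118 for fibroblasts with epithelial cells, fibroblasts with endothelial cells and epithelial with endothelial cells, and the correlations over -0.037 to 0.151, -0.012 to 0.055 and -0.042 to 0.171. Lists called ranged over 8 to 14, 12 to 20 and 9 to 18. The lists that reversed were Cell cycle in epithelial cells without wild-type replicate 2 (adjusted p from 3.12e-08 to 0.178 over the left-out arrays), Immediate early genes in endothelial cells without wild-type replicate 2 (1.46e-05 to 0.934), and Collagens (1.32e-09 to 0.234) and Wnt (0.0061 to 0.912) in endothelial cells without replicate 1 from Pten-null stroma.

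Not run were differences from the 4 arrays of a cell type, which could not be fitted, gene lists with every probe set tested, probe sets chosen by suffix, since their names are numbers, a log offset, since values are log2 already, and the Pten probe sets, which have no name here. Signal over background limits genes near the array median, where the filter changes which are tested.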

Other observations

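The PPAR gamma gene Pparg, singled out after its values were seen, moved in opposite directions in the cultured cells. It fell by 1.26 ± 0.13 (SE, 2 arrays per group) in fibroblasts and rose by 2.04 ± 0.24 in epithelial cultures, a difference of 3.30 ± 0.27 (adjusted p = 0.000205). The epithelial rise started at 4.56, below the array medians, and lay in the arrays with raised fibroblast markers. Wild-type and Pten-null fibroblasts held Pparg at 7.12 and 5.85, so fibroblasts in those cultures may add to the rise. However, the epithelial cultures from Pten-null stroma lay above Pten-null fibroblasts. At the median share set by fibroblast markers, Pten-null fibroblasts predicted a rise of 0.482, so fibroblasts of that profile would not give all of it. The NF-kappa B inhibitor genes Tnfaip3 and Nfkbia, also singled out after their values were seen, rose by 1.76 ± 0.14 and 1.30 ± 0.12 in fibroblasts. Tnfaip3 fell by 1.12 in epithelial cells, a difference of -2.88 ± 0.30 (adjusted p = 0.000852).

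Wnt targets and modulators moved both ways in fibroblasts, with 4 of 16 higher and 3 lower, and 4 and 7 adjusted over the list alone. The secreted Wnt antagonist genes Frzb and Sfrp1 went apart, Frzb at 2.28 ± 0.14 and Sfrp1 at -1.75, and camera did not call the list (adjusted p = 0.325, and adjusted p = 0.901 with an estimated correlation). Secreted growth factors had 4 of 32 higher and 4 lower, 5 and 8 adjusted over the list alone, among them the epidermal growth factor family member Ereg at 2.22 and Igf1 at -0.65 (camera adjusted p = 0.387, and adjusted p = 0.845 with an estimated correlation). PI3K feedback and FOXO targets had 1 of 33 higher, the mitochondrial superoxide dismutase gene Sod2 at 1.82, and 4 lower, among them Cdkn1b, the gene for p27, at -0.57 (camera adjusted p = 0.0534, and adjusted p = 0.806 with an estimated correlation); 1 was higher and 8 lower adjusted over the list alone. The members named here were chosen after their values were seen, from lists fixed beforehand.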
